A study of Homo sapiens with 6 samples.

How the data were processed

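Poly(A)-enriched RNA of LNCaP cells, a human prostate cancer line, was sequenced in 6 libraries. Enzalutamide, a drug for prostate cancer, was given at 5 µM for 14 days to the cells of 3 samples, and the cells of 3 samples received the vehicle dimethyl sulfoxide (DMSO). Per the labels' protocols, 150000 cells were seeded per dish in medium with 10% fetal bovine serum, vehicle was 0.1% DMSO, and medium and drug were refreshed every 72 h. Controls were seeded equally and handled on the same schedule, but were collected at 70 to 80% confluency, per the labels' protocols. Their day of collection and the density of the treated cells are not given in the sources used here, so time in culture and density may differ along with the drug. Total RNA had an integrity number of 10, and 100 ng entered a poly(A) mRNA library kit for paired reads of 100 bases, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

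Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5, featureCounts, Subread 1.6.5 and edgeR 3.20.8 with the hg38 genome. The deposited table gives whole-number read counts per gene and library for 18164 genes, per the file headers. It also gives log2 CPM and log2 RPKM values per library, and the authors' log2 fold change, p-value and false discovery rate, per the file headers. The authors' log2 values and p-values were used here only for comparison with the counts. The table had been filtered before deposit: in each retained gene the third highest count was at least 9. Genes outside it are not analysed here. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain. Of the rows, 236 lie on alternate scaffolds and 255 share a symbol with another row. Reads of such genes can be split or lost. Lists were matched on the primary chromosomes, as written or by gene ID for renamed genes, and 591 of 772 list entries were found.

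Counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by the trimmed mean of M values (TMM), and genes were tested with the robust quasi-likelihood F test on group alone, with 4 residual degrees of freedom. The filterByExpr filter removed none of the 18164 genes, so an alternative without a filter gives no different value. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as past the threshold. Changes are enzalutamide minus DMSO, and CPM values use TMM-scaled library sizes. An SE beside a log2 change was derived from the F test, as the size of the change over the square root of F. It may be too small where a group held few counts. The biological coefficient of variation was 12.3%. Where all 3 libraries of a group held 0 counts, a lower bound of the fold was taken against a floor of 3 counts per library. Where a group held 1 to 3 counts in all, the ratio is given with its exact 95% counting interval. Floors and intervals cover counting error only. No source used here says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

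Before the data were examined, 27 pathway lists and 4 lists of markers of other cell types were fixed, with the design and the first set of alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the 28 lists tested. A correlation estimated from the data and the fry test were alternatives. The estimate lay below the preset value for neuroendocrine markers (-0.044), neuroendocrine lineage regulators (-0.086) and fatty acid synthesis (-0.021). Loss of those 3 calls in that setting therefore does not show correlation between members. For ribosomal proteins (0.60) and glycolysis (0.51) the estimate lay far above the preset value, so their p-values at that value may be far too small. It was also above the preset value for the unfolded protein response (0.050), chromatin regulators (0.092) and long non-coding RNAs (0.099). Named genes followed a rule fixed at the same time. It took a fixed set of prostate, neuroendocrine and proliferation genes, and up to 4 members per list past the threshold with a mean of at least 1 CPM in the higher group, by size of change. It also took the 6 largest changes and the 4 smallest p-values in each direction among protein-coding genes without overlap between groups. Other members of the lists are given as examples. Some genes, and 3 of the lists tested, are not reported here.

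The test was checked on simulated counts for the enzalutamide comparison with 17793 genes in the simulation. It recovered 41.7% of genes changed 1.5-fold, 86.4% of those changed 2-fold and 96.8% of those changed 4-fold. Of the calls, 7.18% were false, and 0 unchanged lists were called, not counting lists that share members with the changed one. Only 233 genes were made to change, far fewer than were called in the real data, so these rates may not carry over. Genes were drawn independently and without GC trends, so the simulation cannot check the list test under correlation between genes.

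Other settings were DESeq2 size factors, upper quartile scaling, library size alone, DESeq2 1.42.0, limma-voom 3.58.1, edgeR's exact test, a stricter filter, the replicate number as a block, leaving out each library, an adjusted p under 0.01, and a test against a log2 change of 1. Settings added after seeing the data were removal of mitochondrial genes, removal of GC content and length trends by a smoother with a span of 0.3, the length trend alone for gene counts, and lists without some members. GC content came from GENCODE transcripts matched by gene ID for 97.2% of genes. Settings for normalized values do not apply to counts. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.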

Results

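Gene expression was measured by RNA sequencing in 6 LNCaP libraries, 3 from DMSO controls and 3 from cells kept in 5 µM enzalutamide for 14 days. Total counts over the 18164 retained genes were 36869889, 42540487 and 35578160 in the DMSO libraries, and 51777719, 52107644 and 42302153 in the enzalutamide libraries. Within a group the lowest correlation of log2 CPM between libraries was 0.987, and between groups the highest was 0.923. The first principal component held 88.4% of the variance and separated the groups. The second held 5.44% and set enzalutamide replicate 1 apart, as the plot of the libraries shows. Mitochondrial genes took 10.8% ± 0.393 (SD, n = 3) of counts in DMSO and 13.8% ± 1.81 (SD, n = 3) with enzalutamide. Pairs of replicates differed by more than sampling noise, with chi-square per degree of freedom of at least 3.79.

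**Figure D1:**
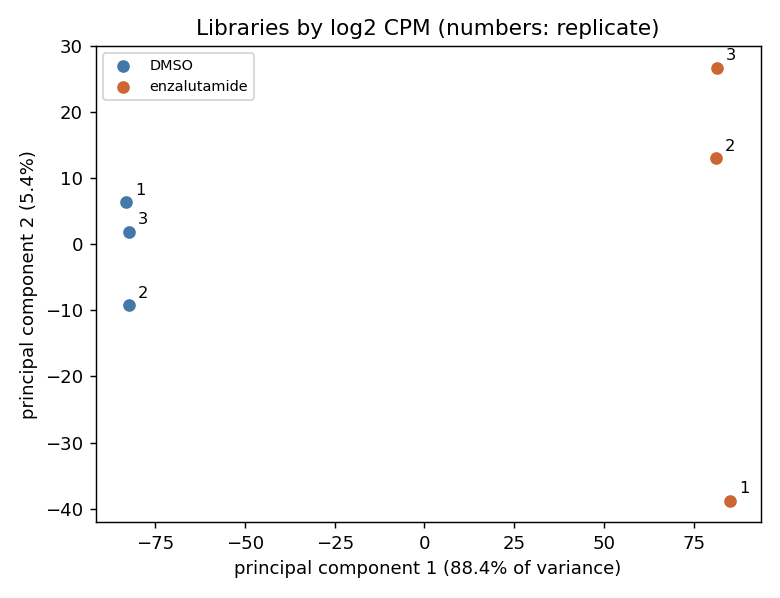
Each point is one library, placed by principal components 1 (88.4% of variance) and 2 (5.44%) of log2 CPM, coloured by group and numbered by replicate. The groups separate along component 1, and enzalutamide replicate 1 lies apart from replicates 2 and 3 along component 2.

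The comparison asks which transcripts differ after 14 days of enzalutamide. Enzalutamide changed 10754 of 18164 genes (edgeR quasi-likelihood test, adjusted p under 0.05): 5450 were higher and 5304 lower. Of these, 2676 were at least 2-fold higher and 2227 at least 2-fold lower. KLK3, which encodes prostate-specific antigen, fell from 2582 ± 21.5 to 194 ± 28.4 CPM (SD, n = 3 per group). MKI67, a proliferation marker, fell from 328 ± 4.72 to 5.69 ± 0.0902 CPM (SD, n = 3 per group). Controls were collected at 70 to 80% confluency, so these differences cannot be separated from possible differences in time in culture and density. In a test against a log2 change of 1, the count was 2965 genes.

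KLK2, a kallikrein protease (chromosome 19, 50861568 to 50880567, hg38), changed by -4.48 ± 0.11 (log2, SE, adjusted p = 1.16e-09). FKBP5, an immunophilin, fell 14.7-fold, and TMPRSS2, a serine protease, fell 3.90-fold. ADAM7 (chromosome 8, 24440930 to 24526970) had 4849, 4617 and 4278 counts in DMSO and 4, 1 and 2 with enzalutamide. The fitted log2 change was -11.23, a size that rests on few counts with enzalutamide. HPGD, which inactivates prostaglandins, changed by -6.79, and STEAP4, a metalloreductase, by -5.23. ORM1 had 155 counts over the DMSO libraries and 1 over the enzalutamide libraries, 201-fold lower (interval 35.5 to 7978). By contrast SGK1 (log2 change 1.87), ACP3 (1.56) and TSC22D3 (0.52) rose. SGK1 and TSC22D3 are known to respond to glucocorticoids, and ACP3 encodes prostatic acid phosphatase.

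OPRK1, the kappa opioid receptor (chromosome 8, 53225716 to 53251697), rose from 1.69 ± 0.278 to 405 ± 23.1 CPM (SD, n = 3 per group). IGFBP3, which binds insulin-like growth factors, rose 73.9-fold. UGT2B17, which conjugates steroids for excretion, rose 40.7-fold, and CCN3 rose 33.5-fold. PRUNE2 fell 2.84-fold, and its reads may be mixed with those of the overlapping PCA3.

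**Figure D2:**
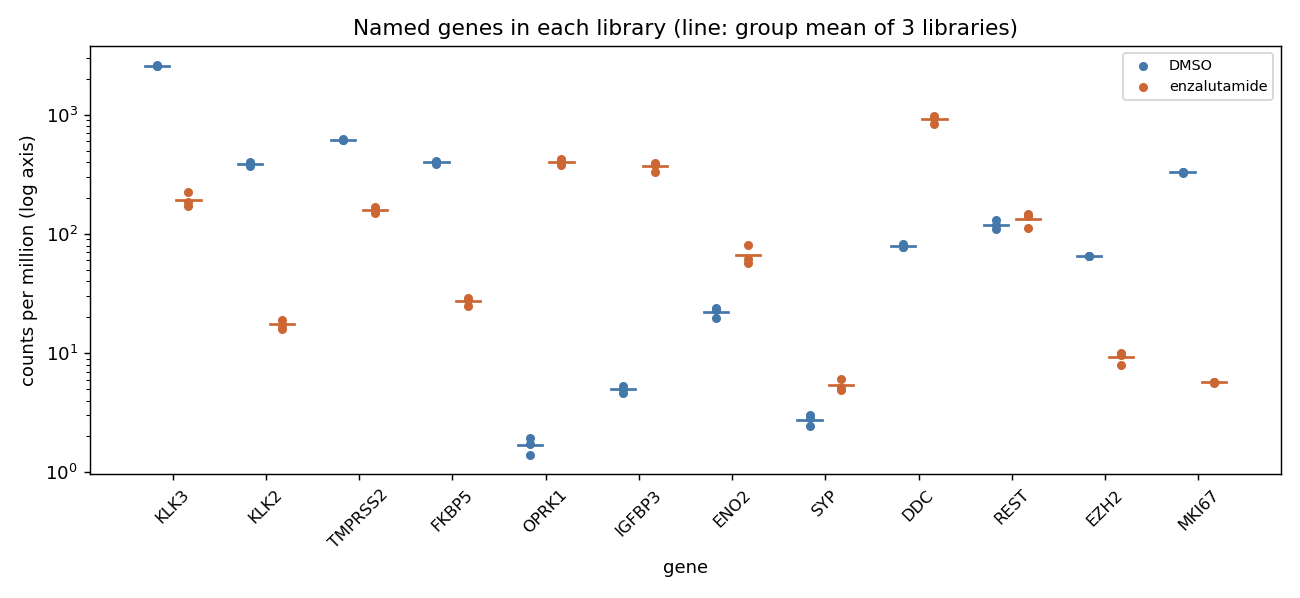
Points are CPM of single libraries on a log axis for 12 named genes, with DMSO and enzalutamide side by side and a line at each group mean of 3 libraries. KLK3 fell from 2582 to 194 CPM and MKI67 from 328 to 5.69, while OPRK1 rose from 1.69 to 405.

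Cell division genes fell almost throughout. All 40 mitosis members fell, with a median of -4.87 (camera adjusted p = 4.15e-118). ASPM, a spindle protein, fell 69.7-fold, HMMR 66.8-fold, DLGAP5 62.0-fold and KIF20A, a kinesin of late division, 59.5-fold. Of 40 DNA replication genes, 39 fell with a median of -2.73 (adjusted p = 5.79e-52), among them MCM10 (log2 change -6.29), CDC45 (-5.49) and RRM2, a subunit of ribonucleotide reductase (-6.10). POLE did not pass (-0.19). Of 28 genes of homologous recombination and the Fanconi anaemia pathway, 27 fell with a median of -2.41 (adjusted p = 2.20e-31), and adjusted over the list alone 28 fell. BRCA2, a DNA repair protein, fell 30.4-fold, EXO1, a nuclease, 35.4-fold and BRIP1, a helicase, 25.9-fold. Replication and mitosis counts adjusted over the list alone were 39 and 40. These 3 lists held with an estimated correlation, with adjusted p = 0.00595 for DNA replication, 0.0057 for mitosis and 0.0116 for recombination.

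Neuroendocrine markers moved in both directions. Of 17 measured members, 12 rose, 2 fell and 3 did not pass, with a median of 1.59 (camera adjusted p = 0.00581; adjusted p = 0.114 with an estimated correlation). The median was 0.75 under the stricter filter and 0.74 without members under a mean of 1 CPM (adjusted p = 0.0126, chosen after seeing the data), and the list passed in both. Counts adjusted over the list alone were 12 and 2. ENO2, neuron-specific enolase, rose from 22.2 ± 2.28 to 67.0 ± 12.8 CPM (SD, n = 3 per group), with reads that may be shared with the overlapping LRRC23, and SYP, a synaptic vesicle protein, from 2.77 ± 0.309 to 5.37 ± 0.641 CPM (SD, n = 3 per group). DDC, a decarboxylase of amine synthesis, rose 11.6-fold, PNMA2 10.7-fold and SSTR2, a somatostatin receptor, 9.15-fold. CHGB rose from 0.0502 to 0.3 CPM, close to the limit of detection. KCND2, a potassium channel, fell 43.4-fold, and VGF changed by -2.15. Without DDC, which is also in another list, 11 of 16 members rose and 2 fell with a median of 1.28, close to the median with it, though the list no longer passed (adjusted p = 0.0647, an alternative chosen after seeing the data). CHGA, NCAM1 and SCG2 were not analysed here.

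Regulators of the neuroendocrine lineage passed camera as a lower list, with 10 of the 28 fixed members measured. Of these 6 fell, 2 rose and 2 did not pass, with a median of -0.49 (camera adjusted p = 0.0166, and 0.153 with an estimated correlation). Adjusted over the list alone, 6 fell and 2 rose. The largest falls were AURKA, a mitotic kinase (10.5-fold), EZH2, a histone methyltransferase (7.11-fold), and HES6 (4.48-fold). AURKA and EZH2 are also in the mitosis and chromatin lists. The list was not tested without them, so a fall of the remaining regulators as a group is not shown. ONECUT2 changed by -0.53 ± 0.13 (log2, SE). REST, a repressor of neuronal genes, did not pass (log2 change 0.16 ± 0.12, SE, adjusted p = 0.278), but passed without enzalutamide replicate 1 (0.29, adjusted p = 0.00014). INSM1, POU3F2 and SOX2 were not analysed here. With limma-voom the list did not pass (adjusted p = 0.137).

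Genes of the neuronal cytoskeleton and synapse did not pass as a list (camera adjusted p = 0.0647), with 14 of 25 rising, 4 falling and the same counts adjusted over the list alone. NLGN1, a synaptic adhesion protein, rose 11.7-fold, SYT11 rose 6.87-fold, and MAP2, a microtubule protein of dendrites, fell 5.47-fold. CNTNAP2, whose reads are split with an alternate scaffold, fell 4.71-fold. The list passed with limma-voom (adjusted p = 0.0238).

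Ribosomal protein genes fell by a common, moderate amount: 28 of 30 fell and 2 did not pass, with a median of -0.80 and quartiles of -0.97 and -0.70 (camera adjusted p = 4.48e-05; adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, 28 fell. RPS2 fell 3.11-fold, RPS19 2.56-fold, RPL32 2.22-fold and RPL14 2.14-fold. The mitochondrial share of counts was higher in the same libraries, as given above. That share includes the mitochondrial ribosomal RNAs, chosen after their values were seen. MT-RNR2 rose from 38394 to 57858 CPM and MT-RNR1 from 3801 to 8949 CPM. Of 13 mitochondrial mRNAs, 1 rose and 12 did not pass (camera adjusted p = 0.714). MT-ATP6 was the one that rose (log2 change 0.40 ± 0.13, SE, adjusted p = 0.0262), and it did not pass without DMSO replicate 1 (0.0961), DMSO replicate 2 (0.0515), DMSO replicate 3 (0.0612) or enzalutamide replicate 3 (log2 change 0.22, adjusted p = 0.0603). None of the mitochondrial mRNAs passed when adjusted over the list alone (0 rose).

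Fatty acid synthesis and glycolysis passed as lower lists with the preset correlation, and neither held with an estimated one. Of 21 fatty acid synthesis genes 13 fell and 4 rose, with a median of -0.93 (camera adjusted p = 0.00091; adjusted p = 0.0752 with an estimated correlation). ELOVL2 and ELOVL7, fatty acid elongases, fell 16.1-fold and 12.6-fold, ACSL3 fell 4.81-fold, and SCD5, a desaturase, rose 17.2-fold. Of 21 glycolysis genes 12 fell and 2 rose, with a median of -0.50 (adjusted p = 0.000757; adjusted p = 0.384 with an estimated correlation). That median was -0.77 without enzalutamide replicate 1 and -0.37 without enzalutamide replicate 3. LDHA, lactate dehydrogenase A, fell 4.13-fold and HK2, hexokinase 2, fell 8.89-fold. SLC2A3 and PDK1 also fell. Of 24 genes of cholesterol synthesis and uptake 15 fell and 3 rose (adjusted p = 0.0647, not past the threshold), and EBP fell 2.81-fold. That list passed with limma-voom (adjusted p = 0.00723) and without enzalutamide replicate 1 (adjusted p = 0.0245). Polyamine synthesis did not pass (adjusted p = 0.284), with SRM, spermidine synthase, 3.57-fold lower and ODC1 2.07-fold lower among 4 falls and 1 rise. Falls adjusted over the list alone numbered 13, 12, 15 and 4 in these lists, and rises 4, 2, 3 and 1.

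FAS, a death receptor, fell 4.91-fold, PLK3 4.11-fold and GDF15 4.05-fold, while CDKN1A, a cell cycle inhibitor, rose (log2 change 0.56). Of 24 unfolded protein response genes 15 fell and 4 rose (camera adjusted p = 0.0481; adjusted p = 0.324 with an estimated correlation), and adjusted over the list alone 16 fell and 4 rose. HSP90B1, a chaperone, fell 2.45-fold and SDF2L1 2.73-fold. That call was lost without DMSO replicate 2 (0.0529), enzalutamide replicate 2 (0.0602) or enzalutamide replicate 3 (0.0554), and with the stricter filter (0.116), DESeq2 (0.0561), upper quartile scaling (0.0694), library size alone (0.0564) or the exact test (0.0541). Cell cycle inhibitors and senescence genes did not pass (adjusted p = 0.189), with 8 of 18 rising and 5 falling, the same counts adjusted over the list alone. LMNB1, lamin B1, changed by -4.46 (log2) and CDKN2B rose 4.30-fold. IL1B, a cytokine, rose from 0.0541 to 2.81 CPM.

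Chromatin regulators passed camera as a lower list but were mixed, with 18 of 33 falling and 11 rising, also adjusted over the list alone (camera adjusted p = 0.0166, and 0.347 with an estimated correlation). The median was -0.37, with quartiles of -1.01 and 0.37. ASF1B, a histone chaperone, fell 23.5-fold, HELLS 9.81-fold and HMGB2 8.47-fold. These were picked by size of change, and the list was not tested without them, so a general fall of chromatin regulators is not shown. The call was lost with limma-voom (0.14). Long non-coding RNAs of prostate and nucleus fell in 9 of 16 and rose in 3, also adjusted over the list alone (adjusted p = 0.0126; adjusted p = 0.296 with an estimated correlation). SCHLAP1 fell 4.19-fold, SNHG1 3.71-fold and PCA3 8.21-fold. The call was lost under the stricter filter (0.0522). Replication-dependent histones did not pass (0.0763), with 9 of 17 falling and 4 rising, and 9 and 5 adjusted over the list alone. H1-5, a linker histone listed as HIST1H1B, fell 108-fold, from 453 counts over the DMSO libraries to 5 over the enzalutamide libraries. The histone list passed without DMSO replicate 3 (0.0435). The libraries were poly(A)-enriched, so histone mRNAs that lack a poly(A) tail may be poorly measured.

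Epithelial and signalling lists did not pass camera. Among luminal genes 10 of 21 rose and 4 fell (adjusted p = 0.367), with CD24 4.80-fold higher, ELF3 3.19-fold higher and GATA2, a transcription factor, 2.36-fold higher. Basal and stemness genes rose in 6 of 11 and fell in 3 (0.132), with ITGB4 10.3-fold and NGFR 5.15-fold higher. Mesenchymal genes fell in 6 of 11 and rose in 3 (0.0952), with TWIST1 7.23-fold and SNAI2 13.2-fold lower, and the list passed without DMSO replicate 1 (0.0402). Interferon genes rose in 13 of 20 and fell in 2 (0.0647), with IRF1 5.31-fold higher and OAS3 4.06-fold lower, and the list passed with limma-voom (0.017) and with the replicate number as a block (0.0446). Wnt and Notch genes rose in 10 of 20 and fell in 7 (0.0952): LEF1, a Wnt-responsive transcription factor, rose 43.7-fold, HEY1 5.47-fold and WNT4 5.03-fold. Growth factor receptors rose in 7 of 14 and fell in 5 (0.975), with RET 7.46-fold higher and IGF1 6.20-fold lower. Steroid receptor and metabolism genes rose in 7 of 17 and fell in 6 (0.988); the median (-0.12) and mean (0.145) differ in sign, and camera gave the downward direction. NR3C1, the glucocorticoid receptor, rose from 0.304 ± 0.123 to 2.02 ± 0.0243 CPM (SD, n = 3 per group). Adjusted over the list alone, rises and falls were 10 and 5 for luminal genes, 7 and 3 for basal genes, and unchanged in number for the other lists of this paragraph.

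Markers of other cell types stayed at low levels. Fibroblast and smooth muscle markers rose in 4 of 7 and fell in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.101): COL3A1 reached 2.92 CPM and TAGLN 12.9 CPM, while COL1A1 fell to 8.60 CPM. FAP had 2 counts over the DMSO libraries and 310 over the enzalutamide libraries, 120-fold higher (interval 32.9 to 993). Endothelial markers had 3 measured members: EMCN rose 4.57-fold, ESAM did not pass and VWF fell 1.56-fold, a call lost without DMSO replicate 2 (0.0528) or enzalutamide replicate 2 (0.0561). Of 4 markers of basal-like epithelial lines, KRT14 and TGM2 fell, ANXA1 did not pass and VIM rose, and the last call was lost without DMSO replicate 1 (0.0855), 2 (0.116) or 3 (0.0556) or enzalutamide replicate 1 (0.0592). Adjusted over the list alone, 1 endothelial marker rose and 1 fell, and 1 rose and 2 fell in the last list. Leukocyte markers had 0 members measured on the primary chromosomes. HLA-DRA, a member of that list, had 2 rows on alternate scaffolds and was not counted. Both held 0 counts in DMSO and rose, to 2.38 and 0.57 CPM, with enzalutamide.

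**Figure D3:**
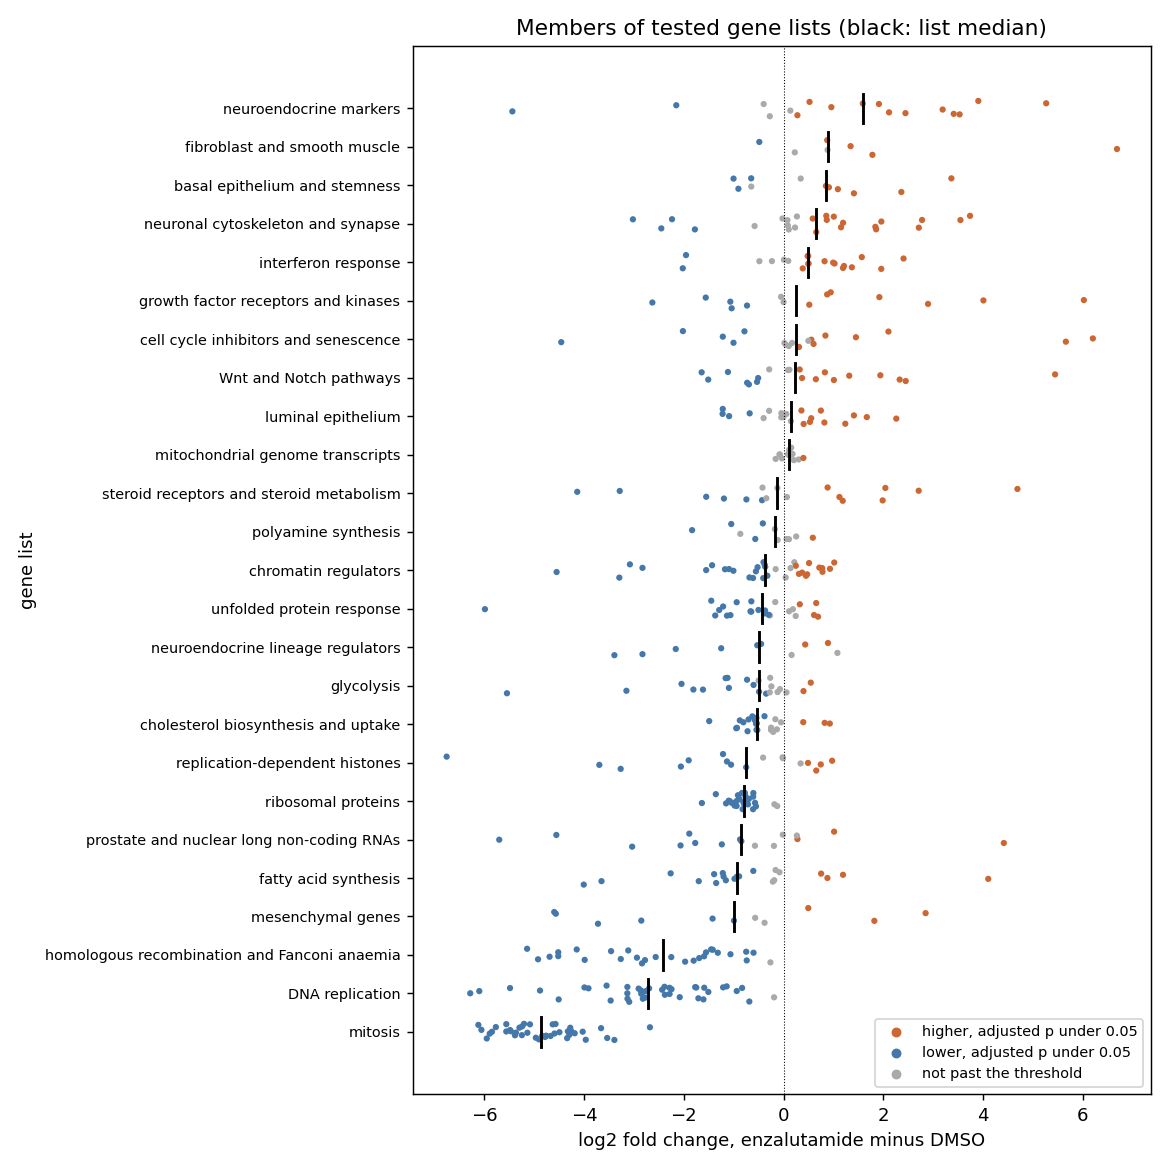
Each point is one member of a list shown, placed by its log2 fold change (enzalutamide minus DMSO) and coloured by direction where its adjusted p was under 0.05, with a black line at the list median. Mitosis (median -4.87) and DNA replication (-2.73) lie lowest, with neuroendocrine markers (1.59) highest.

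Among protein-coding genes without overlap between groups, SHH, a secreted morphogen (chromosome 7, 155799980 to 155812463), had the largest fitted rise. It had 0 counts in each DMSO library and 2801, 2887 and 2001 with enzalutamide, at least 652-fold higher. The largest rises and falls here were picked by fitted log2 change, so ranks are uncertain where a group held few or 0 counts. EVX1, also at 0 in DMSO, was at least 15.4-fold higher. CD200, an immune receptor ligand, had 1 count over the DMSO libraries and 878 over the enzalutamide libraries, 678-fold higher (interval 121 to 26813). AOC1 (log2 change 8.46) and PCDH11X (8.37) followed. HLA-DRA, on an alternate scaffold and therefore uncertain, was at least 30.0-fold higher. After ADAM7, the lowest fitted changes were in SLC38A4 (1291-fold lower, interval 231 to 51039) and CCDC141 (575-fold lower, interval 159 to 4754). SPC25, a symbol with several rows, came next (fitted log2 change -8.62), at least 18.3-fold lower. OR51E1 (log2 change -8.02) and ORM2 (313-fold lower, interval 55.7 to 12427) followed. The smallest p-values also picked MATN2 and TENM2, higher by 7.37 and 7.28, and TMEFF2 and TNFRSF19, at -6.92 and -6.41. MATN2 overlaps RPL30, so its reads are uncertain.

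Camera called 14 of 28 lists, 2 higher and 12 lower. With an estimated correlation 5 held, among them DNA replication, mitosis and homologous recombination. In the authors' deposited table, 11226 genes had a false discovery rate under 0.05, and 10752 of these also passed here in the same direction.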

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

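Removal of GC and length trends, removal of mitochondrial genes, the length trend for gene counts, and the lists without some members were chosen after seeing the data. The counts of changed, higher and lower genes stayed within 1.5 times under every scaling, test, filter and adjusted p tried except the test against a log2 change of 1, with 2965 changed, 1647 higher and 1318 lower, where a larger change is asked for. Leaving out 1 library gave 9151 to 12924 changed genes, the highest without enzalutamide replicate 1. Upper quartile scaling moved the median of all genes from -0.00 to 0.12 and gave 6409 higher and 4370 lower genes. The number of lists called was 9 at an adjusted p under 0.01, 5 with an estimated correlation and 24 with fry, which asks another question, and 12 to 15 otherwise. With the replicate number as a block, 10174 genes changed and 15 lists passed. Deviations of same-numbered libraries correlated at -0.15, -0.144 and 0.051, which gives no sign of pairing by number. Pairing is not excluded, since the deviations also follow GC content and are tied to each other within a group.

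The median of neuroendocrine markers moved from 1.59 to 0.75 under the stricter filter. The direction of the camera test turned in lists that did not pass, and the cause was not tested. For growth factor receptors the medians were -0.037 under the stricter filter, 0.27 with DESeq2, 0.22 without the length trend and 0.13 without GC and length trends, and on leaving out 1 library 0.19 (without enzalutamide replicate 1, where it turned) to 0.31 (without DMSO replicate 3). For steroid receptors and metabolism they were -0.22 under the stricter filter, -0.12 under the replicate block, with DESeq2 and without GC and length trends, and -0.14 (without DMSO replicate 3) to -0.064 (without enzalutamide replicate 1) on leaving out 1 library. For mitochondrial mRNAs the median was 0.017 without enzalutamide replicate 3 and 0.21 without enzalutamide replicate 1. Depth limits genes near the floor of 3 counts, such as CHGB. Changed protein-coding genes were longer among the higher than the lower calls at each of 4 levels of expression, for example medians of 4661 against 3838.5 bases at the lowest.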

Other observations

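The genes of these first 2 paragraphs were chosen after their values were seen. MYC, a regulator of growth, fell 8.79-fold (log2 change -3.14 ± 0.13, SE), and NPM1 and NCL, abundant nucleolar proteins, changed by -1.56 and -1.35. Surface proteins moved apart: MME rose from 778 to 2990 CPM, STEAP2 from 1586 to 3129 and FOLH1, prostate-specific membrane antigen, from 1454 to 2314, and CD276 changed by 0.81. STEAP1 did not pass (0.04), while EGFR (-0.73) and PSCA (-0.90) fell. GRPR, the gastrin-releasing peptide receptor, changed by -6.45.

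Single genes that rose from near 0 were ROR2, to 13.6 CPM, SIX2, to 4.20, and DACH1, to 3.40. PLA2G2A, a secreted phospholipase, rose from 8.09 to 1235 CPM. MT-RNR1 and MT-RNR2, the mitochondrial ribosomal RNAs, rose by 1.24 and 0.59 (log2), and 15 of 20 mitochondrial tRNAs rose, while small nucleolar RNA genes had a median of -0.95 with 2 rising and 26 falling of 50. Small nuclear RNA genes had a median of -0.03 with 7 rising and 8 falling of 42. Poly(A) enrichment is not suited to counting such small RNAs, and their reads may come from overlapping genes, so these values are uncertain. Long non-coding RNA genes rose in 1187 and fell in 632 of 3379, and processed pseudogenes rose in 85 and fell in 319 of 821.

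The splits of the libraries, the tests of enzalutamide replicate 1 and the lists without DDC or without members under 1 CPM were chosen only after the results were seen, and the other tests in this part before their own values were seen. With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split called 10754 genes, 5450 higher and 5304 lower, and the highest other split 0 in each case (1 of the 10 splits as large). For lists the real split called 14 and the highest other split 12 (1 of 10 as large). Each other split sets 2 libraries of a group and 1 of the other against the reverse, so part of the difference between the groups stays in it, and these counts are no reference without an effect.

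Enzalutamide replicate 1 stood apart from replicates 2 and 3. Lower depth is argued against, since its total count was 1.10 times the mean of the others. Its deviation from the group mean correlated across genes with GC content (Spearman 0.825, genes not being independent replicates), and the SD of the deviation fell from 0.257 to 0.142 once GC and length trends were removed. GC correlations were also large in enzalutamide replicates 2 (-0.778) and 3 (-0.704) and DMSO replicate 2 (0.635), and deviations from a mean of 3 are tied to each other. A GC bias that differs between libraries is thus a candidate explanation for part of the difference, without showing which library carries it, and no biological explanation was tested.

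Ribosomal protein genes were lower as a list, a call lost with an estimated correlation (adjusted p = 0.39). A GC bias is argued against, since their median was -0.87 once GC and length trends were removed, against -0.80 before. The length used was the deposited gene length, such as 8626 bases for RPL14 and 2388 for RPS2, which may differ from that of their mRNAs. A bias by mRNA length was thus not tested. A candidate explanation is lower output of the whole ribosome production programme, though only mRNA levels were measured. Of 40 ribosome biogenesis factors, 35 fell and 1, UBTF, rose (log2 change 0.52), with a median of -0.84 (camera p = 1.22e-07, and p = 0.00368 with an estimated correlation). The mRNA fall was thus shared by these factors, which does not show its cause. These 40 were listed without looking up their values, though other nucleolar genes had been seen to fall. The drug, culture time and density remain open as sources, untested.

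Neuroendocrine markers were higher as a list, a call lost with an estimated correlation (adjusted p = 0.114). The estimate was -0.044, below the preset 0.01, so the loss does not show correlation between members. A general rise of weakly expressed genes is argued against as the sole source: their median of 1.59 lay at percentile 99.99 of 10000 random lists matched on mean expression, whose 95th percentile was 0.58. The size of the rise rests on weakly expressed members, as the median was 0.75 under the stricter filter and 0.74 without members under a mean of 1 CPM. Without DDC the median was 1.28, with 11 of 16 rising and 2 falling, though the list did not pass (adjusted p = 0.0647). Drug, culture time and density cannot be separated here.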
